A study of Mus musculus with 22 samples.

How the data were processed

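Strand-specific polyadenylated RNA of mouse hepatocytes was read as 75 bp single-end reads in 22 libraries from wild-type and Ezh1/2 mutant animals of both sexes at postnatal day 14 and 2 months. The deposited table of raw counts holds whole numbers of reads per gene symbol, and per the submitters' processing notes STAR 2.4.2a, HTSeq 0.6.1p1, DESeq2 1.14.1 and bedtools were used with the mouse build mm9. The roles of these tools, the annotation and the strand setting are not given in the sources used here. The second deposited table holds a signal per gene that the authors made by dividing each count by a size factor per library. The ratio of the raw to the normalized value was checked to be 1 constant per library (largest relative spread 1.07e-09), and these factors ran from 0.576 to 2.31. The exons removed in the mutants are not given in the sources used here, and the tables are per gene, so the deletion was read only as a gene-level count. No annotation of mm9 was used. Chromosome membership came from a GRCm38 gene table, which held 12930 of the tested symbols, and no coordinates are given. The count table has 24422 entries, of which 5824 were at 0 in every library, 27 have a symbol that was turned into a date and 2 symbols appear more than 1 time.

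Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (13493 tested) and scaled by TMM (factors 0.765 to 1.24). A single quasi-likelihood model with 8 age, genotype and sex groups was fitted to all 22 libraries (14 residual degrees of freedom), and groups of 2 libraries are assumed to vary like the others. The replicates, described below, did not vary alike in all groups. The comparisons were mutant against wild-type at each age, M2 against P14 in each genotype, the change of the genotype effect with age, males against females in each genotype at M2 and in wild-type at P14, and the change of the sex difference with genotype. Contrasts other than those of sex weight the sexes equally. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fitted log2 fold changes use edgeR's prior count of 0.125, and principal components and list scores use log2 CPM with a prior count of 2. Where every library of a group was at 0, the fold is a bound against 3 counts over the group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels mark replicates as biological but do not say whether each is a separate animal, so the p-values measure the spread between these samples. The titles' replicate numbers recur in several groups, but of 62 pairs with the same number 11 correlated above 0.1 after group means were removed (median −0.02), so the numbers were not taken as pairs.

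The design, the comparisons, 27 gene lists of 537 members (536 in the table) and the rule for named genes were fixed before the data were examined. The lists cover PRC2 subunits, homeobox and other developmental regulators, fetal genes, functions and zones of adult hepatocytes, sex-biased genes, cell cycle, CDK inhibitors and p53 response, matrix, markers of other liver and blood cells, acute phase and immediate early genes. They were tested over 5 comparisons with camera (preset correlation 0.01, and with an estimated correlation) and fry on voom values, adjusted over all lists and comparisons. No list passed camera with an estimated correlation in any comparison. By rule, the genes to name were Ezh1, Ezh2, Eed and Suz12, the 6 genes per direction with the largest called change among those with a mean log2 CPM of at least 2 and groups that do not overlap, up to 2 called members per direction of each list with a mean log2 CPM of at least 0, and for the interaction and sex comparisons the 5 genes per direction with the smallest p. The rule named 283 pairs of a gene and a comparison from the values, of which the text gives at least 119. The others were left to the counts of their lists and comparisons, some because the call was lost without several single libraries and the rest for length, a choice made after their values were seen. A few of them are not reported here. The text gives at least 89 genes.

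Sex labels were checked with Xist and 4 Y-linked genes. The 4 genes summed to at most 4 counts in females and at least 1194 in males, and Xist had at most 47 counts in males and at least 15402 in females. Replicates differed by more than counting error, with a chi-square per gene of at least 13.4 over 23 pairs of replicates. It was 13.4 in M2 wild-type males, 18.0 in M2 wild-type females and 30.3 to 66.1 in M2 mutants. At P14 it was 16.4 to 50.0 in wild-type males, 15.4 in wild-type females and 23.0 to 75.8 in mutant females, so the ranges of the genotypes overlapped. In P14 mutant males it was 239, from a pair that includes male 1, the library with the highest share of the ribosomal transcript Rn45s (32.6%). The spread shared by all groups can thus be too wide for M2 wild-type and too narrow for mutants. Albumin took 9.76% to 17.8% of the counts. The test was tried on simulated counts with the depth of these libraries and 1 spread per gene in all groups, with 100 genes changed 2-fold and 100 changed 4-fold. Of these it called 74 and 96 for the mutant at P14, 66 and 97 for the mutant at M2, 67 and 96 for age in wild-type, 75 and 99 for age in mutant, 30 and 84 for the change of the genotype effect with age, 24 and 83 for sex in wild-type at M2, 46 and 85 for sex in mutant at M2, 8 and 63 for the change of the sex difference and 36 and 93 for sex in wild-type at P14. Between 1 and 12 unchanged genes were called in each. The simulation drew every gene on its own and had no unequal spread between groups. It does not show the rate of false calls in the real libraries.

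Alternatives chosen beforehand were DESeq2 size factors in edgeR, 2 other low-count filters (none, and at least 10 counts in 5 libraries), the DESeq2 Wald test, limma-voom, limma-trend on log2 of the deposited normalized values plus 1, only the groups compared, an additive or no sex term, males or females only, an absolute log2 fold change of at least 1, the replicate number as a block, each library left out in turn, a threshold of 0.01 for overlaps, and 12 splits of the wild-type P14 libraries. Alternatives added after seeing the data were the removal of the ribosomal entries Rn45s, Mir6236 and Lars2, a covariate made of the mean of the Kupffer, endothelial, stellate, lymphocyte and granulocyte lists, leaving out P14 mutant male 1 for its Rn45s share, leaving out M2 mutant males 1 and 3, and 4 splits of the wild-type M2 libraries. All 22 columns of both tables were used.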

Results

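Polyadenylated RNA was sequenced from mouse hepatocytes, the main metabolic cells of the liver, at postnatal day 14 (P14) and at 2 months (M2). The mice were wild-type or carried the Alb-Cre transgene, which drives recombination in hepatocytes, with Ezh1 deleted and Ezh2 floxed. These mice are called mutants here. Ezh1 and Ezh2 encode the alternative methyltransferases of Polycomb repressive complex 2 (PRC2), which deposits the repressive H3K27 methylation mark, and the series title frames the question as postnatal maturation of hepatocytes. The 22 libraries fell into 8 groups. At P14 there were 3 wild-type males, 2 wild-type females, 2 mutant males and 5 mutant females. At M2 there were 2 wild-type males, 2 wild-type females, 3 mutant males and 3 mutant females. The total count per library ran from 6946003 (M2 mutant male 3) to 27505582 (M2 mutant female 1). Levels are CPM (counts scaled to the TMM-adjusted library total) as mean ± SD, with n = 5 for P14 wild-type, n = 7 for P14 mutant, n = 4 for M2 wild-type and n = 6 for M2 mutant unless stated. Fold changes are log2 values that weight males and females equally, with standard error (SE) and Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test over 13493 genes.

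Age and genotype were the main axes of variation. The first principal component held 35.8% of the variance and the second 25.4%. Xist and 4 Y-linked genes matched the sex label in 22 of 22 libraries. Replicates of a group correlated at r = 0.929 to 0.991 across genes, which are not independent replicates. The ribosomal transcript Rn45s took 6.19% to 32.6% of the counts. Its share was highest in P14 mutant male 1, and 18.5% was the next highest value. The 6 M2 mutant libraries carry another label format than the other 16, and no library of another group shares it, so a batch and the M2 mutant group cannot be told apart.

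**Figure D1:**
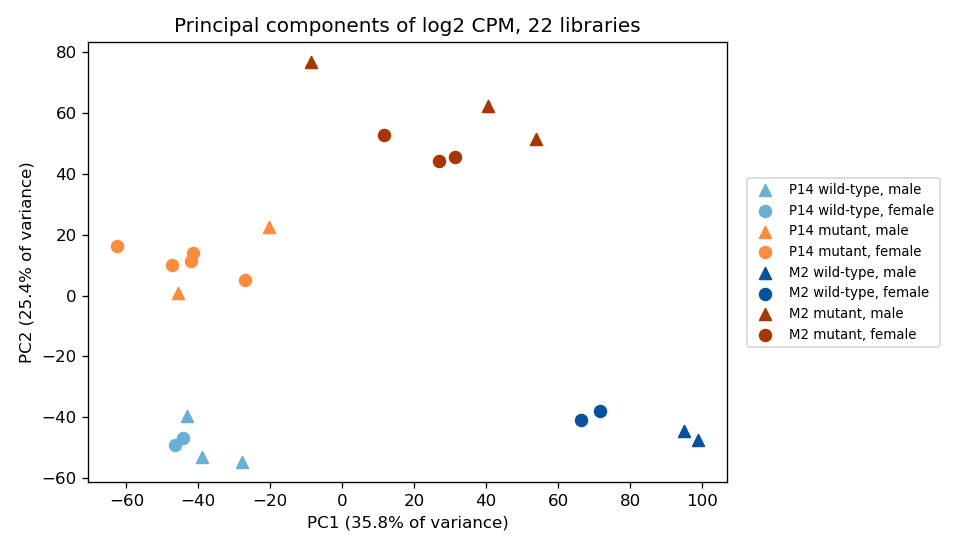
Each point is 1 of the 22 libraries, placed by the first (x axis, 35.8% of the variance) and second (y axis, 25.4%) principal component of log2 CPM, coloured by age and genotype, with triangles for males and circles for females. Mutants lie above wild-type libraries on the second component at both ages.

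Ezh1 transcript, the gene deleted in all cells, was low in every mutant library. At P14 it fell from 10.2 ± 0.603 CPM in wild-type to 0.947 ± 0.295 CPM in mutants (log2 fold change −3.40, SE 0.23, adjusted p = 5.73e-09). At M2 it fell from 8.55 ± 1.37 to 1.34 ± 0.404 CPM (−2.70, SE 0.21, adjusted p = 1.84e-08). Ezh2 measured 8.68 ± 1.05 CPM in wild-type and 5.54 ± 1.25 CPM in mutants at P14 (−0.64, SE 0.19, adjusted p = 0.0231). The Ezh2 call was lost without wild-type female 2 (adjusted p = 0.0988) or mutant male 2 (adjusted p = 0.12). At M2 Ezh2 measured 4.72 ± 1.18 and 4.59 ± 0.82 CPM (−0.03, adjusted p = 0.928), and the sign turned without M2 wild-type male 2 (0.23), wild-type female 1 (0.05), mutant male 3 (0.08) or mutant female 1 (0.05). Counts are per gene and include exons outside any deleted part, so an Ezh2 count near the wild-type level does not check the genotype label. Of the core partners, Eed did not pass at P14 (−0.17, adjusted p = 0.47) and fell at M2 from 16.2 ± 1.01 to 10.6 ± 1.81 CPM (−0.62, SE 0.14, adjusted p = 0.00186). Suz12 did not pass at either age (−0.06, adjusted p = 0.83, and −0.22, adjusted p = 0.237), although it was called lower at M2 without mutant male 3 (adjusted p = 0.0441).

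In mutants at P14, homeobox and other developmental regulators, which PRC2 represses in many tissues, rose together. Of 47 tested, 36 were higher and 0 lower than in wild-type. The list has 86 members, and the others did not pass the low-count filter. Of the 47 tested, 24 had 0 counts in every library of a P14 genotype. A gene at 0 in wild-type passes the filter only through other groups and cannot be called lower. The counts and tests of this list depend on that filter. Sox17, an endoderm and endothelial regulator, rose from 0.766 ± 0.326 to 2.74 ± 0.478 CPM (1.72, SE 0.33, adjusted p = 0.000871). Pax6, an eye and brain regulator, had 0 counts in all 5 wild-type libraries and was at least 58.8-fold higher in mutants, taking 3 counts over the group as the floor. On the same floor Irx5 was at least 44.4-fold, Hoxa10 at least 26.8-fold and Hoxd9 at least 26.4-fold higher. Pax6, Irx5, Hoxa10 and Hoxd9 were chosen after their values were seen. The number higher was 40 when adjusted over the list alone. The median log2 fold change was 4.95, or 2.68 with genes at 0 in a group set at their bound (camera adjusted p = 1.19e-21; adjusted p = 0.135 with an estimated correlation). Without mutant male 2, 20 members were higher.

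Part of the acute phase genes, whose products the liver secretes in inflammation, were also higher at P14. Of 20 tested, 9 were higher, 0 lower and 11 not called. The orosomucoid genes rose most, with Orm1 at 2.06 ± 1.33 CPM in wild-type and 220 ± 231 CPM in mutants (6.86, SE 0.61, adjusted p = 1.74e-07) and Orm3 at 0.221 ± 0.154 and 14.9 ± 5.2 CPM (6.09, SE 0.36, adjusted p = 1.92e-09). Among genes outside the list, the iron hormone hepcidin gene Hamp went from 0.277 ± 0.322 to 58.1 ± 127 CPM (7.79, SE 1.13, adjusted p = 6.19e-05). Its copy Hamp2 went from 1.03 ± 0.445 to 43.0 ± 31.8 CPM (5.57, SE 0.44, adjusted p = 4.23e-08), and the serine protease inhibitor gene Serpina3c went from 0.149 ± 0.142 to 80.3 ± 104 CPM (adjusted p = 0.000426). Limma-voom lost the calls of Serpina3c (adjusted p = 0.281) and Hamp (adjusted p = 0.0706). With age in wild-type 8 of the 20 acute phase genes rose, including Orm1 (8.56) and Orm3 (4.74), and 6 fell. Hamp rose with age as well (12.1). For Orm1, Orm3 and Hamp an acute phase change was not separated from a change in maturation. Reads of near-identical copies, such as those of the Orm and Hamp genes, could be split between them in counting, so the share of each copy is uncertain. Of acute phase genes 9 were higher and 1 lower adjusted over the list alone (median 0.70, camera adjusted p = 0.000836, adjusted p = 0.448 with an estimated correlation). Granulocyte markers rose with them, 8 of 11 higher, including Mpo, the myeloperoxidase of neutrophil granules (1.13 ± 0.349 to 8.60 ± 5.98 CPM, adjusted p = 0.000834), and the granule protease gene Prtn3 (1.08 ± 0.21 to 5.02 ± 2.06 CPM, adjusted p = 5e-05). With p adjusted over the list alone 10 were higher (median 1.67, camera adjusted p = 2.41e-05, adjusted p = 0.381 with an estimated correlation), and 4 were higher without mutant male 1.

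Several genes of fat synthesis were higher in mutants at P14, and genes of cholesterol synthesis in part of the mutant libraries. The mean log2 CPM of the cholesterol synthesis list was 5.49 to 7.34 in male 2 and females 3, 4 and 5, but 3.62 to 4.14 in male 1 and females 1 and 2, not above the 3.63 to 4.47 of wild-type libraries, a comparison chosen after seeing the data. The mean of the lipogenesis list was 5.63 to 7.38 in mutants and 5.08 to 5.63 in wild-type libraries. Scd1, the desaturase that makes monounsaturated fatty acids, rose from 14.9 ± 4.08 to 648 ± 687 CPM (5.67, SE 0.72, adjusted p = 1.31e-05), and Thrsp, a regulator of lipogenesis, from 26.3 ± 11.2 to 310 ± 242 CPM (3.64, SE 0.63, adjusted p = 0.000376). Elovl5, a fatty acid elongase, fell from 441 ± 52.0 to 260 ± 39.9 CPM (−0.85, SE 0.16, adjusted p = 0.000723). Of 14 lipogenesis genes 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone (median 0.63, camera adjusted p = 0.0469, adjusted p = 0.623 with an estimated correlation). Of 17 cholesterol synthesis genes 15 were higher and 0 lower, the same numbers adjusted over the list alone (median 2.19, camera adjusted p = 0.000305, adjusted p = 0.565 with an estimated correlation). They included the squalene epoxidase gene Sqle (5.48 ± 3.5 to 56.1 ± 84.9 CPM, 3.89, SE 0.999, adjusted p = 0.00923). These groups rested on few libraries. Without mutant male 2 the number of higher cholesterol genes was 2 and of lipogenesis genes 3, without wild-type female 1 the number of cholesterol genes was 4, and without wild-type female 2 the numbers were 6 and 3. Sqle was lost without each of the same libraries (adjusted p = 0.454, 0.0703 and 0.0668).

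Fetal and neonatal hepatocyte genes moved in both directions in mutants at P14, with 4 of 16 higher and 3 lower. The desaturase gene Scd2 rose from 4.73 ± 0.923 to 29.9 ± 31.8 CPM (2.81, SE 0.69, adjusted p = 0.00695) and Cd24a, a surface glycoprotein gene, from 2.74 ± 0.843 to 5.19 ± 1.6 CPM (0.97, adjusted p = 0.0256). Scd2 was lost without wild-type female 2 or mutant male 2 (adjusted p = 0.0512 and 0.227). Cd24a was lost without wild-type male 1, either wild-type female or mutant male 1 (adjusted p = 0.0627, 0.0875, 0.0931 and 0.112). Afp, the fetal serum protein alpha-fetoprotein, fell from 136 ± 72.1 to 5.03 ± 2.398 CPM (−4.93, SE 0.39, adjusted p = 4.71e-08). Igf2, a fetal growth factor, measured 654 ± 313 and 599 ± 445 CPM (−0.42, adjusted p = 0.71), with a value of 0.00 without mutant male 2, and Gpc3, a fetal heparan sulfate proteoglycan, 84.9 ± 13.8 and 74.9 ± 16.1 CPM (−0.26, adjusted p = 0.336). Gpc3 was called lower without mutant male 1 (−0.62, adjusted p = 0.00817). The counts were the same adjusted over the list alone (median −0.34, mean 0.38, camera adjusted p = 0.171, adjusted p = 0.649 with an estimated correlation). The number higher was 2 without wild-type female 2 or mutant male 2, and the number lower was 6 without mutant male 1. Outside the list, the steroid dehydrogenase gene Hsd3b1 fell from 62.6 ± 25.7 to 9.33 ± 6.2 CPM (−2.66, adjusted p = 0.00016). Socs2, a feedback inhibitor of growth hormone signalling, fell from 57.2 ± 16.5 to 11.2 ± 9.41 CPM (−2.30, adjusted p = 0.00272), and Ppara, the nuclear receptor of fatty acid oxidation, from 330 ± 20.04 to 193 ± 43.1 CPM (−0.85, adjusted p = 0.000471). Nlrp12 (−2.54, adjusted p = 1.74e-07), Arrdc4 (−2.34, adjusted p = 7.33e-06) and Acnat2 (−2.17, adjusted p = 0.00144) were also among the largest falls.

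Some genes of the adult hepatocyte were already raised in P14 mutants. The glutathione transferase gene Gsta2 rose from 0.388 ± 0.197 to 9.14 ± 4.35 CPM (4.51, SE 0.55, adjusted p = 7.88e-06). Nnmt, which methylates nicotinamide, rose from 4.82 ± 1.95 to 79.4 ± 70.0 CPM (4.17, SE 0.73, adjusted p = 0.000392). As groups the phase II conjugation genes (7 of 30 higher, 4 lower) and cytochrome P450 genes (7 of 32 higher, 3 lower) did not pass camera (adjusted p = 0.269 and 0.224; adjusted p = 0.803 and 0.684 with an estimated correlation). The counts adjusted over the list alone were 8 and 5 for phase II and 12 and 6 for cytochrome P450 genes. The lower phase II count was 2 without wild-type female 2 or mutant male 1. For cytochrome P450 genes, 3 were higher without wild-type female 1, and the number lower was 6 without wild-type male 3 and 1 without wild-type female 1, wild-type female 2 or mutant male 2. Cell cycle genes were lower, 7 of 31, also adjusted over the list alone (median −0.90, camera adjusted p = 8.63e-08, adjusted p = 0.448 with an estimated correlation), among them the cyclin gene Ccna2 (24.3 ± 7.83 to 9.96 ± 5.21 CPM, −1.31, adjusted p = 0.0202). The number lower was 1 without wild-type female 2, 2 without mutant male 1 or mutant male 2, and 11 without mutant female 4, and Ccna2 itself was lost without the first 3 of these (adjusted p = 0.118, 0.0671 and 0.0665).

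Over all genes, the number of genes higher in mutant at P14 was 1588 and of genes lower in mutant at P14 was 929. The counts were 1042 and 491 without wild-type female 1, 1039 and 508 without wild-type female 2, and 986 and 481 without mutant male 2. Markers of Kupffer cells and macrophages were higher for 5 of 13 (7 adjusted over the list alone, median 0.64, camera adjusted p = 0.0027, adjusted p = 0.565 with an estimated correlation), a number that was 0 without wild-type female 1 or mutant male 1, 1 without wild-type male 1 or wild-type female 2, and 3 without wild-type male 2. Endothelial markers were higher for 2 of 12 (1 adjusted over the list alone, median 0.59, camera adjusted p = 0.0216, adjusted p = 0.623 with an estimated correlation), and for 0 without wild-type male 1, either wild-type female or mutant male 1, and 1 without wild-type male 2, wild-type male 3 or mutant female 1, 2, 3 or 5. Camera passed 8 of the 27 lists at P14. Of these, fry did not pass cholesterol synthesis (fry adjusted p = 0.0911), lipogenesis (0.107), cell cycle (0.0623), Kupffer (0.0919) and endothelial lists (0.176).

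At M2 fetal genes that wild-type hepatocytes had silenced were higher in mutants, although most of these genes fell with age in mutants too. Gpc3 measured 0.236 ± 0.15 CPM in wild-type and 25.9 ± 5.4 CPM in mutants (6.85, SE 0.32, adjusted p = 2e-11). Igf2bp3, an RNA-binding protein of fetal tissue and tumours, measured 0.497 ± 0.784 and 20.6 ± 5.38 CPM (adjusted p = 3.79e-09). Igf2 measured 0.0983 ± 0.126 and 6.88 ± 8.67 CPM (adjusted p = 0.00542). Of 16 fetal and neonatal hepatocyte genes 12 were higher and 0 lower, or 13 and 0 adjusted over the list alone (median 3.57, or 3.49 at the bound, camera adjusted p = 2.41e-05, adjusted p = 0.2 with an estimated correlation). Outside the list, Sult2a6, a sulfotransferase gene with close paralogs, had 0 counts in all 4 wild-type libraries and 7.72 ± 7.16 CPM in mutants, at least 139-fold higher. Ntrk2, the receptor of brain-derived neurotrophic factor, rose from 5.44 ± 6.37 to 118 ± 23.8 CPM (6.03, SE 0.33, adjusted p = 1.5e-10), and A2m, the protease inhibitor alpha-2-macroglobulin, from 0.0373 ± 0.044 to 20.4 ± 8.03 CPM (adjusted p = 7.9e-06).

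Developmental regulators were higher at M2 as well, with 43 of 47 higher and 0 lower. The limit of the low-count filter holds here too, since 31 of the 47 had 0 counts in every library of an M2 genotype. Lhx2, a LIM homeobox gene, rose from 0.401 ± 0.239 to 4.34 ± 0.972 CPM (3.57, SE 0.35, adjusted p = 2.63e-07). Hoxa10 was at least 136-fold, Zic1 at least 129-fold, Pax6 at least 64.4-fold and Hoxd9 at least 58.4-fold higher than wild-type libraries at 0 counts, and these 4 were chosen after their values were seen. With p adjusted over the list alone 44 were higher (median 7.25, or 4.68 at the bound, camera adjusted p = 3.07e-24, adjusted p = 0.135 with an estimated correlation).

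Genes of the mature hepatocyte were lower in mutants at M2 across several functions. Markers of other liver cells were higher in the same comparison. With those markers as a covariate, the numbers of lower metabolic genes were much smaller, as given with the matrix genes below. The part of other cell types in these falls was not separated. Of 7 urea cycle genes 6 were lower and 0 higher, including Asl, argininosuccinate lyase (587 ± 72.2 to 178 ± 42.9 CPM, −1.73, SE 0.14, adjusted p = 2.94e-08), and Arg1, arginase (1158 ± 190.5 to 368 ± 152 CPM, −1.72, SE 0.17, adjusted p = 1.76e-07). The transcription factor gene Hnf4a, a main regulator of hepatocyte identity, fell from 648 ± 69.7 to 309 ± 21.8 CPM (−1.07, SE 0.11, adjusted p = 6.16e-07), and Foxa3 by less (−0.75, adjusted p = 3.89e-05). In all, 7 of 15 hepatocyte transcription factors were lower and 1 higher. Pygl, liver glycogen phosphorylase, fell from 440 ± 21.9 to 131 ± 16.9 CPM (−1.75, adjusted p = 4.66e-08). Cyp27a1, an enzyme of bile acid synthesis, fell from 493 ± 15.2 to 144 ± 70.9 CPM (−1.86, SE 0.22, adjusted p = 2.4e-06), Cyp2c38 from 103 ± 71.7 to 20.1 ± 12.1 CPM (−2.13, adjusted p = 3.18e-05) and the glucuronosyltransferase gene Ugt2b1 by 1.90 on the log2 scale (adjusted p = 7.52e-06). Cyp4a31, a fatty acid hydroxylase gene with close paralogs, rose (2.02, adjusted p = 1.78e-05). Thrsp, higher in mutants at P14, was lower at M2, 518 ± 93.2 against 84.1 ± 55.3 CPM (−2.75, adjusted p = 0.000834).

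The test over these lists was camera, with the count adjusted over the list alone after the main one. Urea cycle genes (6 lower, 6 adjusted over the list alone) had a median of −0.84 and camera adjusted p = 0.000555, with adjusted p = 0.197 with an estimated correlation. Hepatocyte transcription factors (7 lower, 7) had a median of −0.52 and adjusted p = 0.00652, with adjusted p = 0.197 with an estimated correlation. Cytochrome P450 genes (13 of 32 lower, 13, with 2 higher) had a median of −0.51 and adjusted p = 0.00255, with adjusted p = 0.417 with an estimated correlation. Phase II conjugation genes (17 of 30 lower, 19, with 3 higher) had a median of −0.61 and adjusted p = 0.000212, with adjusted p = 0.443 with an estimated correlation, and 11 were lower without M2 wild-type male 2 or mutant male 1. The 3 higher were 1 without any single M2 wild-type library. Bile acid genes (8 of 16 lower, 8, with 2 higher) had a median of −0.66 and adjusted p = 0.0027, with adjusted p = 0.308 with an estimated correlation. Genes of gluconeogenesis and glycogen (5 of 10 lower, 6) had a median of −0.44 and adjusted p = 0.00255, with adjusted p = 0.197 with an estimated correlation, and 3 were lower without wild-type male 2, wild-type female 2 or mutant male 1. Lipogenesis genes (6 of 14 lower, 6, with 1 higher) had a median of −0.74 and adjusted p = 0.0235, with adjusted p = 0.565 with an estimated correlation. Cholesterol synthesis (1 of 17 higher, 0 adjusted over the list alone, adjusted p = 0.965) and acute phase genes (2 of 20 higher and 4 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.438) did not pass. The acute phase count was 2 lower without either wild-type male, wild-type female 2, mutant male 1, mutant female 1 or mutant female 2.

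Among genes that mark the position of hepatocytes along the lobule, most called pericentral genes were higher and most called periportal genes lower at M2. Of 15 pericentral genes, expressed around the central vein, 10 were higher and 2 lower. The higher ones included the ammonium transporter gene Rhbg (2.92 ± 0.195 to 22.3 ± 5.95 CPM, 2.93, adjusted p = 1.06e-06) and the dicarboxylate transporter gene Slc13a3 (4.67 ± 2.93 to 26.2 ± 14.3 CPM, 2.67, adjusted p = 1.39e-05). The 2 lower ones were Slco1b2 (−1.09) and Cyp2e1 (−0.49). Of 12 periportal genes 6 were lower and 1 higher, including Cyp2f2 (1394 ± 382 to 426 ± 277 CPM, −1.72, adjusted p = 0.000509) and the protease gene Ctsc (150 ± 81.9 to 66.6 ± 22.3 CPM, −1.05, adjusted p = 8.11e-05). With age in wild-type Rhbg and Slc13a3 fell (−1.80 and −5.55) and Cyp2f2 rose (2.63). For these genes a change by position cannot be told apart from a change in maturation. Adjusted over the list alone the pericentral counts were 10 and 2 (median 0.97, camera adjusted p = 0.00996, adjusted p = 0.197 with an estimated correlation) and the periportal counts 7 lower and 1 higher (median −0.64, camera adjusted p = 0.00452, adjusted p = 0.197 with an estimated correlation).

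Matrix genes and markers of other liver cells were higher in M2 mutants. Of 37 extracellular matrix and fibrosis genes 31 were higher and 1 lower, with the collagen gene Col1a1 at 0.259 ± 0.00414 and 3.34 ± 4.57 CPM (3.41, SE 0.76, adjusted p = 0.00154) and the annexin gene Anxa2 at 2.21 ± 0.515 and 25.7 ± 11.6 CPM (3.51, SE 0.32, adjusted p = 8.91e-08). Of 9 cholangiocyte (bile duct cell) markers 7 were higher, with osteopontin (Spp1) at 4.75 ± 1.51 and 98.6 ± 49.2 CPM (4.31, SE 0.46, adjusted p = 7.58e-07) and the tight junction gene Cldn7 at 0.0165 ± 0.0331 and 6.57 ± 3.82 CPM (adjusted p = 1.55e-06). All 13 Kupffer cell and macrophage markers were higher, including the scavenger receptor gene Marco (2.09, adjusted p = 0.000198) and Cd74, the MHC class II invariant chain (22.5 ± 5.47 to 73.0 ± 55.5 CPM, 1.72, adjusted p = 0.00275). Stellate cell markers were higher for 9 of 11, including the neurotrophin receptor gene Ngfr (1.98, adjusted p = 0.0095, lost without mutant male 1 with adjusted p = 0.0593) and Hhip (1.80, adjusted p = 0.00587). Lymphocyte markers were higher for 11 of 12 and granulocyte markers for 10 of 11. Mpo had 0 counts in all 4 wild-type libraries and 1.05 ± 0.762 CPM in mutants, at least 18.9-fold higher, and lactoferrin (Ltf) measured 0.0161 ± 0.0321 and 1.48 ± 0.71 CPM (adjusted p = 1.98e-05). Endothelial markers were higher for 2 of 12 (0 adjusted over the list alone and 0 without wild-type male 1, either wild-type female, mutant male 1 or mutant female 1, and 1 without mutant female 2, median 0.34, camera adjusted p = 0.482), and of 6 erythroid markers 2 were lower (2 lower and 1 higher adjusted over the list alone, median 0.33 with camera pointing down, adjusted p = 0.329).

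For these lists camera gave adjusted p = 1.9e-06 for matrix genes (median 1.68), 0.000305 for cholangiocyte (median 3.95, or 3.20 at the bound) and for Kupffer markers (median 1.12), 0.0027 for stellate (median 1.51), 0.00469 for lymphocyte (median 2.07) and 0.00147 for granulocyte markers (median 5.01, or 4.05 at the bound). In the same order the values were adjusted p = 0.424, 0.197, 0.467, 0.424, 0.562 and 0.447 with an estimated correlation. The counts adjusted over the list alone were 31 higher and 1 lower, 7, 13, 9, 11 and 10. The lymphocyte count was 6 without wild-type male 1 or mutant female 2, 7 without wild-type male 2, and 4 without wild-type female 1 or mutant male 1. Without M2 mutant males 1 and 3 together, an alternative chosen after seeing the data, 19 matrix, 8 Kupffer, 4 stellate and 7 lymphocyte genes were higher. With the mean of the Kupffer, endothelial, stellate, lymphocyte and granulocyte markers as a covariate, also chosen after seeing the data, the numbers were 5, 0, 1 and 0, with 39 developmental regulators, 9 fetal genes, 6 cholangiocyte and 4 granulocyte markers still higher. With that covariate the lower counts were 2 for cytochrome P450, 5 for phase II, 3 for bile acid, 2 for urea cycle, 2 for gluconeogenesis and glycogen and 1 for lipogenesis genes. Calls lost with the covariate were those of Eed (adjusted p = 0.249), Igf2 (adjusted p = 0.194), Thrsp (adjusted p = 0.222), Cyp2f2 (adjusted p = 0.164), Col1a1 (adjusted p = 0.399), Cd74 (adjusted p = 0.864), Hhip (adjusted p = 0.563) and Cdkn1a (adjusted p = 0.132).

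Among other lists at M2, 8 of 15 genes of the CDK inhibitors and p53 response were higher, the same number adjusted over the list alone, including Cdkn1a, the inhibitor p21 (2.93 ± 1.57 to 12.6 ± 6.81 CPM, 2.09, SE 0.46, adjusted p = 0.00136; list median 1.0201, camera adjusted p = 0.0106, adjusted p = 0.313 with an estimated correlation). Immediate early genes, which answer acute stimuli, were higher for 8 of 17, also adjusted over the list alone (median 0.89, camera adjusted p = 0.0377, adjusted p = 0.566 with an estimated correlation). At P14 the same list had 7 higher and 1 lower and did not pass (median 0.69, camera adjusted p = 0.0742). Cell cycle genes were higher for 10 of 31 and lower for 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.23), and the number higher was 4, 2 and 3 without wild-type male 1, wild-type male 2 and wild-type female 2, 2 without mutant male 1 and 5 without mutant female 1. The number lower was 1 without wild-type male 1 or wild-type female 1. PRC2 subunits were lower for 4 of 11, also adjusted over the list alone (median −0.22, camera adjusted p = 0.059), and 2 without wild-type male 1 or wild-type female 1. The largest falls outside the lists were in the major urinary protein gene Mup3 (9086 ± 6646 to 655 ± 763 CPM, −4.00, SE 0.57, adjusted p = 1.99e-05), whose reads could be split with its paralogs in counting. Others were the carboxylesterase gene Ces1b (154 ± 18.8 to 20.6 ± 10.8 CPM, −2.93, adjusted p = 1.75e-06), Slc17a8 (−2.87, adjusted p = 3.42e-06), the methyltransferase gene Inmt (824 ± 295 to 125 ± 48.0 CPM, −2.73, adjusted p = 1.22e-07) and the phosphatase gene Acp1 (43.3 ± 5.17 to 6.88 ± 1.59 CPM, −2.68, adjusted p = 4.14e-09). The number of genes higher in mutant at M2 was 3321 and of genes lower in mutant at M2 was 2749. The number lower was 1713, 1691, 1829 and 1659 without wild-type male 1, male 2, female 1 and female 2. With a fold of at least 2 (an absolute log2 fold change of at least 1), 2427 were higher and 344 lower.

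**Figure D2:**
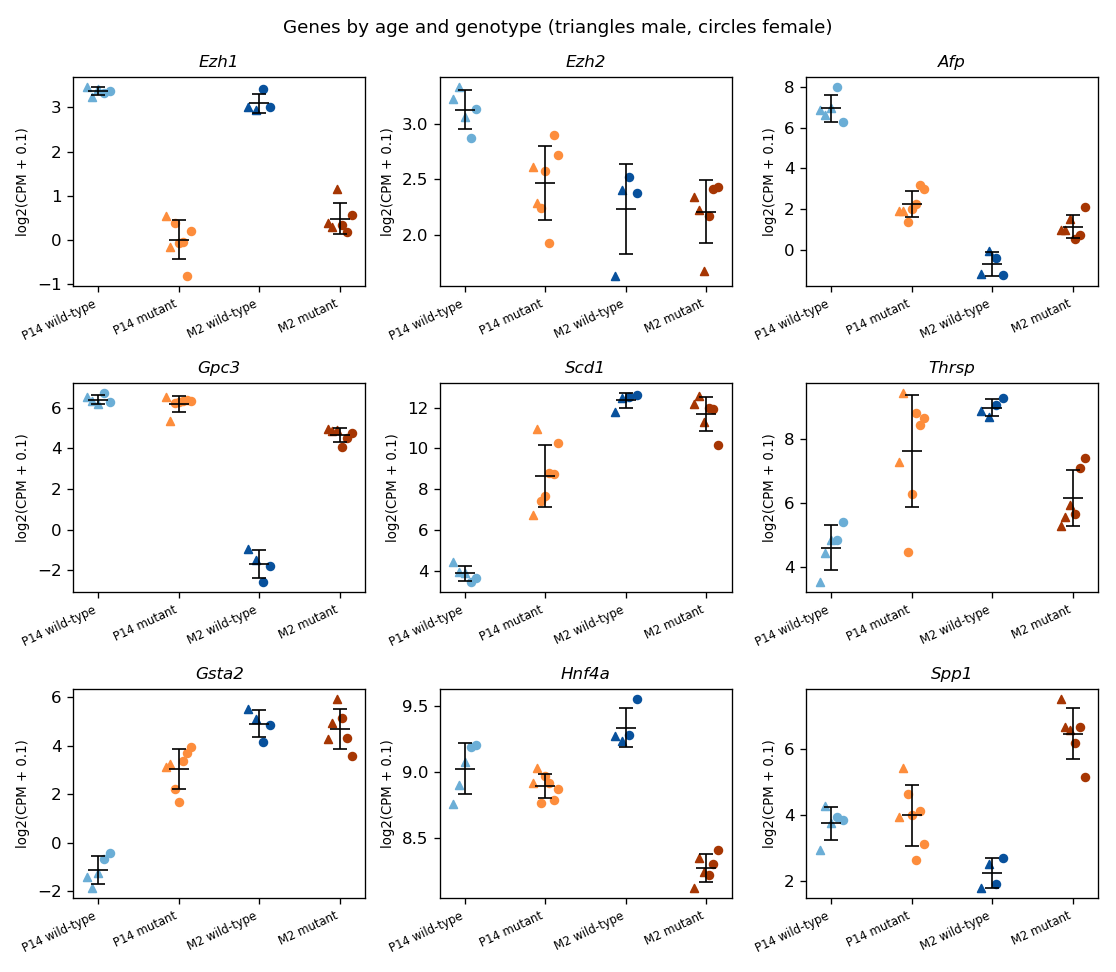
Each panel shows log2(CPM + 0.1) of a gene in the 22 libraries (y axis) by age and genotype (x axis), with triangles for males, circles for females, and the mean ± SD of the plotted values as bars. Ezh1 was low in every mutant library, Gpc3 was near 0.236 CPM in M2 wild-type only, and Hnf4a was lower in all 6 M2 mutants.

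**Figure D3:**
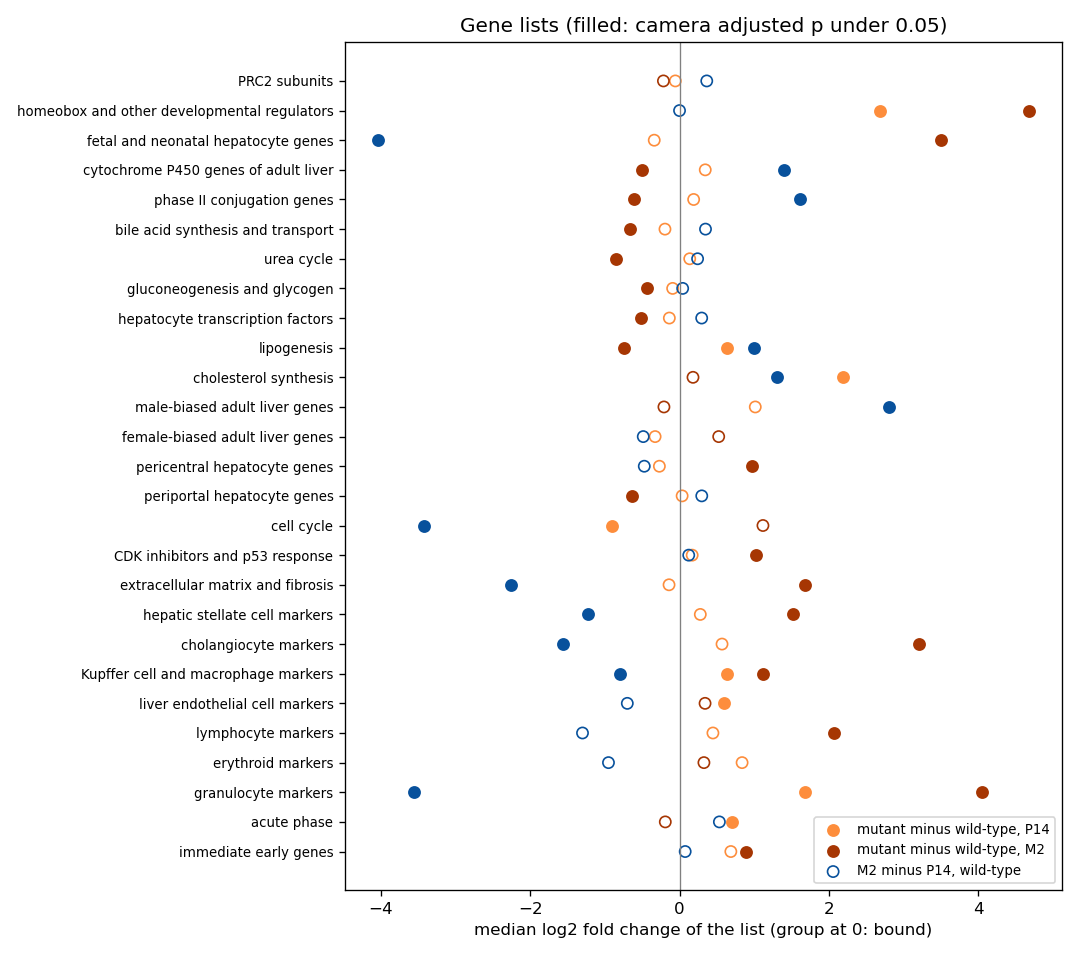
Each point is the median log2 fold change (x axis) over the tested members of a fixed gene list (y axis) in mutants at P14, in mutants at M2 and with age in wild-type, with genes at 0 in a group set at their bound. Filled points passed camera with the preset correlation, and no list passed with an estimated correlation. Fetal genes had medians of −0.34, 3.49 and −4.04.

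From P14 to M2 in wild-type hepatocytes, fetal genes were silenced and some groups of adult metabolic genes rose. Igf2 fell from 654 ± 313 to 0.0983 ± 0.126 CPM, the imprinted noncoding RNA gene H19 from 5988 ± 1270.2 to 0.494 ± 0.377 CPM (adjusted p = 7.67e-07 and 3.5e-09). Gpc3 fell from 84.9 ± 13.8 to 0.236 ± 0.15 CPM (−8.60, SE 0.32, adjusted p = 6.73e-13) and Afp from 136 ± 72.1 to 0.548 ± 0.264 CPM (−7.98, SE 0.53, adjusted p = 2.25e-09). Hsd3b1 fell from 62.6 ± 25.7 to 0.147 ± 0.112 CPM (adjusted p = 5.61e-08) and Sult2a6 from 7.62 ± 3.03 CPM to 0 counts in all 4 libraries (adjusted p = 2.52e-06). Of 16 fetal genes 12 fell and 0 rose, or 13 and 0 adjusted over the list alone (median −4.15, or −4.04 at the bound, camera adjusted p = 4.91e-08, adjusted p = 0.197 with an estimated correlation). Scd1 rose from 14.9 ± 4.08 to 5350.4 ± 1235 CPM (8.57, SE 0.84, adjusted p = 2.34e-07). Hamp rose from 0.277 ± 0.322 to 899 ± 137 CPM (adjusted p = 5.16e-07), the organic anion transporter gene Slco1a1 from 0.238 ± 0.149 to 535 ± 497 CPM (adjusted p = 2.1e-08) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 91.6 ± 21.6 to 538 ± 269 CPM (2.44, SE 0.59, adjusted p = 0.002). The urinary protein genes Mup3 (1.99 ± 1.28 to 9086 ± 6646 CPM), Mup20 (0.366 ± 0.187 to 2913 ± 3285 CPM) and Mup10 (0.0118 ± 0.0264 to 458 ± 273 CPM) also rose (adjusted p = 1.32e-08, 1.12e-08 and 2.64e-08). The PRC2 gene Ezh2 fell (−0.87, SE 0.21, adjusted p = 0.00229) and Eed rose (0.74, SE 0.15, adjusted p = 0.000523). Ezh1 (−0.26, adjusted p = 0.295) and Suz12 (0.36, adjusted p = 0.0558) did not pass, and Suz12 was called higher without P14 wild-type male 2 (adjusted p = 0.0344).

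Detoxification genes rose with age, 20 of 32 cytochrome P450 genes (2 fell) and 25 of 30 phase II genes (1 fell). Cyp2c38 rose from 0.179 ± 0.135 to 103 ± 71.7 CPM (8.69, SE 0.54, adjusted p = 9.12e-10). Cyp2c54 rose from 12.6 ± 2.69 to 384 ± 19.6 CPM (4.91, SE 0.70, adjusted p = 1.73e-05), Gsta2 from 0.388 ± 0.197 to 31.6 ± 11.4 CPM (6.25, SE 0.56, adjusted p = 7.29e-08) and Nnmt from 4.82 ± 1.95 to 101 ± 32.2 CPM (4.32, SE 0.75, adjusted p = 0.000124). Cyp2c genes have close paralogs. Adjusted over the list alone, 21 cytochrome P450 genes rose and 3 fell (median 1.39, camera adjusted p = 6.42e-07, adjusted p = 0.197 with an estimated correlation) and 25 phase II genes rose and 1 fell (median 1.61, camera adjusted p = 2.17e-10, adjusted p = 0.245 with an estimated correlation). Male-biased liver genes rose for 16 of 17, with 1 lower, also adjusted over the list alone (median 2.80, camera adjusted p = 3.24e-07, adjusted p = 0.197 with an estimated correlation). Lipogenesis genes rose for 8 of 14 and cholesterol genes, including Sqle (5.48 ± 3.5 to 53.8 ± 37.1 CPM, adjusted p = 0.00944), for 10 of 17, with 1 lower in each and the same counts adjusted over the list alone (medians 0.996 and 1.30, camera adjusted p = 0.0148 and 0.0147, adjusted p = 0.565 and 0.668 with an estimated correlation). The lipogenesis count was 5 without M2 wild-type female 1. Other metabolic lists did not pass. Urea cycle genes rose for 2 of 7 (0 to 3 without single libraries, camera adjusted p = 0.521), genes of gluconeogenesis and glycogen for 3 of 10 with 3 lower (camera adjusted p = 0.772), and bile acid genes for 6 of 16 with 4 lower (2 without M2 wild-type male 2, camera adjusted p = 0.106).

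Proliferation, matrix, stellate and granulocyte genes fell with age in wild-type. Cell cycle genes fell for 28 of 31, including the kinase gene Aurkb (8.21 ± 2.14 to 0.237 ± 0.151 CPM, −5.07, SE 0.61, adjusted p = 2.48e-06) and the anaphase activator gene Cdc20 (12.0 ± 3.41 to 0.538 ± 0.47 CPM, −4.64, SE 0.75, adjusted p = 5.86e-05). Matrix genes fell for 25 of 37 and rose for 2, including Col1a1 (8.34 ± 2.7 to 0.259 ± 0.00414 CPM, −4.98, SE 0.76, adjusted p = 3.09e-05) and the metalloprotease gene Mmp2 (−4.56, adjusted p = 3.18e-05). Stellate markers fell for 7 of 11, with Ngfr at 5.28 ± 0.793 and 0.53 ± 0.193 CPM (−3.29, adjusted p = 0.000131). Granulocyte markers fell for 11 of 11, with Mpo at 1.13 ± 0.349 CPM and then 0 counts. The counts of these lists adjusted over the list alone were the same. Camera gave adjusted p = 2.54e-08 (cell cycle, median −3.42), 7.14e-07 (matrix, median −2.25), 0.00255 (stellate, median −1.23) and 0.00039 (granulocyte, median −5.49, or −3.56 at the bound), and adjusted p = 0.443, 0.424, 0.443 and 0.424 with an estimated correlation. Lymphocyte markers (3 of 12 lower, 0 adjusted over the list alone, and 0 to 5 without single libraries, camera adjusted p = 0.133) and erythroid markers (2 of 6 higher and 3 lower, camera adjusted p = 0.88) did not pass. The number of genes higher at M2 in wild-type was 3226 and of genes lower at M2 in wild-type was 3511. With the other cell types' markers as a covariate, chosen after seeing the data, the counts were 1307 and 1387, 12 phase II and 0 cholesterol genes rose, 3 stellate and 6 granulocyte markers fell. The calls of Ezh2 (adjusted p = 0.12), Eed (adjusted p = 0.137), Cyp7a1 (adjusted p = 0.72) and Sqle (adjusted p = 0.549) were then lost.

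In mutants 2688 genes were higher and 2686 lower at M2 than at P14. Of 16 fetal genes 10 fell and 0 rose with age in mutants, or 11 and 0 adjusted over the list alone (median −1.19, camera adjusted p = 0.000187, adjusted p = 0.306 with an estimated correlation), and 1 rose without P14 mutant male 2, P14 mutant female 4 or M2 mutant male 3. The number of genes with genotype effect differing by age was 2930, 1562 with a more positive and 1368 with a more negative value at M2, and without M2 wild-type female 2 the number was 1952. The imprinted growth regulator gene Grb10 measured 61.8 ± 11.4 CPM in wild-type and 28.9 ± 4.01 CPM in mutants at P14 and 2.63 ± 0.531 against 20.01 ± 4.81 CPM at M2 (difference of effects 4.07, SE 0.25, adjusted p = 3.14e-09). Cd63, a tetraspanin gene, measured 48.1 ± 9.02 and 35.8 ± 9.12 CPM at P14 and 1.19 ± 0.238 and 29.0 ± 6.84 CPM at M2 (4.92, SE 0.31, adjusted p = 3.14e-09). Ntrk2 (5.37), Bicc1, an RNA-binding protein gene (4.61), and Igf2bp3 also had a more positive effect at M2 (adjusted p = 3.67e-08, 2.07e-07 and 1.02e-07). In the other direction, the proline dehydrogenase gene Prodh went from 35.5 ± 18.5 and 279 ± 51.6 CPM at P14 to 139 ± 12.3 and 67.7 ± 9.59 CPM at M2 (−4.02, SE 0.33, adjusted p = 1.7e-07). Hamp2 (−6.61), Orm3 (−5.50) and Sntg2 (−3.94) followed (adjusted p = 1.5e-07, 1.87e-07 and 2.07e-07).

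By list, the difference of effects was called positive for 10 of 16 fetal genes and for 21 of 37 matrix genes, and negative for 6 of 7 urea cycle, 7 of 14 lipogenesis and 9 of 20 acute phase genes. No fetal, matrix, urea cycle or acute phase gene was called the other way, and 1 lipogenesis gene was. Adjusted over the list alone the counts were 12, 25, 6, 10 and 11. Camera gave adjusted p = 1e-06, 1.7e-07, 0.000114, 0.000336 and 0.000262, and adjusted p = 0.197, 0.424, 0.197, 0.424 and 0.424 with an estimated correlation. The matrix count was 13 without M2 wild-type male 1 or M2 mutant male 1.

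The genotype effects at the 2 ages were compared with each other and with normal maturation. At both ages 881 genes were higher and 323 lower in mutants, where lists independent of each other would share 391 and 189, and 265 genes were called with opposite signs. These 2 comparisons share no library, and their fold changes correlated across genes at r = 0.519, with covariance 0.683. Set against age in wild-type, the P14 mutant effect shared 553 higher and 448 lower genes (independent lists 380 and 242). Against maturation, 284 genes higher in P14 mutants fell with age and 108 lower genes rose (independent lists 413 and 222). The P14 mutant and wild-type age comparisons share the 5 wild-type P14 libraries. The covariance of fold changes was 0.285, against a median of 0.0627 in 20 simulations of unchanged groups, while the same sign was seen for 54.5% of genes, against 66.2% in the simulations. With the wild-type P14 libraries split in 12 ways so that no library was used in both, the median number shared was 423, against 216 for independent lists. The median share of genes with the same sign was then 54.0%. The M2 mutant effect went against maturation. Of genes higher in M2 mutants 1673 fell with age, and of genes lower in M2 mutants 1468 rose with age (independent lists 864 and 657), with covariance −1.03 against −0.10 in simulations that share the M2 wild-type libraries. The share of genes with the same sign (28.2%) was below the 29.2% to 30.9% of the simulations, while the correlation (r = −0.526) was less negative than their −0.633 to −0.575. Over the 4 splits of the M2 wild-type libraries, with no library in both comparisons, the medians were −1.12 for the covariance, −0.503 for the correlation and 29.1% for the same sign.

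Sex differences of adult liver were present in wild-type at M2 and smaller for several genes in mutants. Selenbp2, a selenium-binding protein gene, measured 655 ± 201 CPM in 2 wild-type males and 7.94 ± 2.06 CPM in 2 wild-type females (6.36, SE 0.47, adjusted p = 3.04e-08), and 66.5 ± 30.6 and 16.5 ± 6.61 CPM in 3 mutant males and 3 mutant females (2.01, SE 0.32, adjusted p = 0.00113). For Selenbp2 the difference of these differences was −4.36 (SE 0.51, adjusted p = 0.00025). Cyp4a12a, a fatty acid hydroxylase gene with a near copy, measured 360 ± 10.4 and 0.163 ± 0.0427 CPM in wild-type males and females and 468 ± 122 and 21.2 ± 10.5 CPM in mutants (adjusted p = 0.00104 for the change). The female-biased cytochrome gene Cyp2b9 measured 1.11 ± 0.593 and 738 ± 105 CPM in wild-type males and females and 35.2 ± 13.4 and 413 ± 154 CPM in mutants (change 5.81, SE 0.59, adjusted p = 6.08e-05). The sulfotransferase gene Sult2a2 measured 0.213 ± 0.301 and 231 ± 42.6 CPM and then 13.1 ± 10.5 and 74.0 ± 34.1 CPM (adjusted p = 0.000556 for the change), and the nucleotidase gene Nt5e 3.13 ± 1.11 and 46.6 ± 4.81 CPM and then 12.5 ± 2.18 and 20.5 ± 5.92 CPM (3.19, SE 0.44, adjusted p = 0.00109). Hsd3b5, a male-biased steroid dehydrogenase gene, measured 263 ± 7.45 CPM in wild-type males and 0.786 ± 0.385 CPM in wild-type females (8.38, SE 0.65, adjusted p = 5.14e-08). Ntrk2 (5.30, adjusted p = 0.00025) and Evc, a gene of Hedgehog signalling (3.08, adjusted p = 0.00311), differed by sex in wild-type at low levels, 0.301 and 10.6 CPM and 0.344 and 2.77 CPM in males and females, and measured 126 and 111 CPM and 13.5 and 12.7 CPM in mutant males and females.

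Some genes still differed by sex in mutants, C6 and Slc22a27 by less than in wild-type. The complement gene C6 was male-biased in wild-type (4.27, SE 0.35, adjusted p = 1.22e-07) and in mutants (2.11, SE 0.26, adjusted p = 6.44e-05), and Slc22a27, an organic anion transporter gene, female-biased in both (−7.79, adjusted p = 5.14e-08, and −3.74, adjusted p = 2.67e-05). The fatty acid elongase gene Elovl3 was male-biased in mutants (7.84 ± 6.37 CPM in males, 0.115 ± 0.0492 CPM in females, adjusted p = 2.83e-05) and in wild-type (adjusted p = 5.08e-05). The oestrogen receptor gene Esr1 was female-biased in mutants (12.9 ± 1.49 and 58.8 ± 14.2 CPM, −2.19, adjusted p = 4.25e-06) and in wild-type (−1.61, adjusted p = 0.000726). The kinase gene Sgk2 was male-biased in mutants (44.8 ± 0.765 and 13.4 ± 1.8 CPM, 1.74, adjusted p = 8.81e-06) but did not pass in wild-type (0.22, adjusted p = 0.688). Sult2a2 differed by sex in mutants as well (−2.53, SE 0.46, adjusted p = 0.00435), a call lost, like that of Selenbp2, when only the groups compared were fitted (adjusted p = 0.0985 and 0.0701).

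The number of genes differing by sex in wild-type at M2 was 327 (164 higher in males), the number of genes differing by sex in mutant at M2 was 245 (153 higher in males) and the number of genes with sex difference changed in mutant at M2 was 67. Of the sex genes, 85 were called in both genotypes with the same direction and 0 with opposite directions. Of the 67 genes, 51 also differed by sex in wild-type. The male-biased list was higher in M2 mutants than in wild-type for 5 of 17 and lower for 6, and the female-biased list for 5 and 6 of 23, the same counts adjusted over the list alone (camera adjusted p = 0.52 and 0.931, with camera pointing down and a median of 0.52 for the female-biased list). Without wild-type male 2 or wild-type female 2 the last count was 3. With groups of 2 or 3 libraries these counts moved with the method and with single libraries. When only the groups compared were fitted, the number was 2642 in wild-type and 87 in mutant. The main counts of 327 and 245 thus depend on the spread shared by all groups. The DESeq2 Wald test gave 372 in mutant and 243 for the change. Without wild-type male 1, male 2, female 1 and female 2 the wild-type number was 107, 118, 135 and 135. Without mutant male 1, male 2, male 3, female 1, female 2 and female 3 the mutant number was 141, 101, 1232, 129, 101 and 140. The number for the change was 12 without wild-type male 1 or male 2, 19 and 32 without wild-type female 1 and female 2, 760 without mutant male 3 and 34 without mutant female 1. At P14, 5 genes differed by sex in wild-type, the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty in males and Xist in females.

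**Figure D4:**
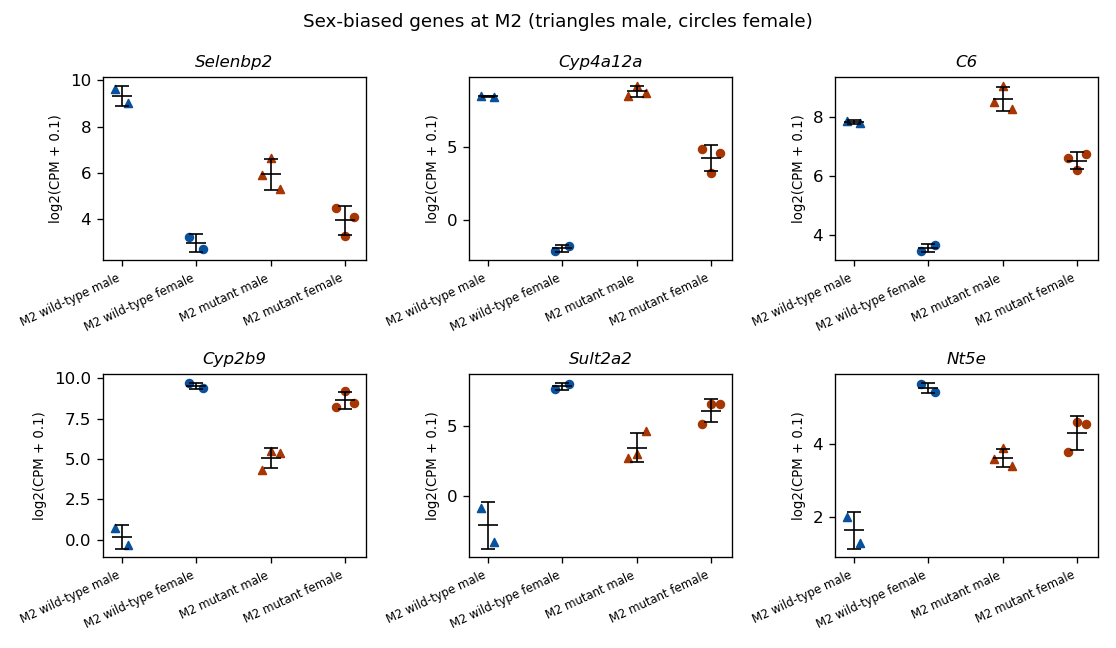
Each panel shows log2(CPM + 0.1) of a gene in the 10 libraries of M2 (y axis) by genotype and sex (x axis), with triangles for males, circles for females, and the mean ± SD of the plotted values as bars. Selenbp2 differed by a log2 value of 6.36 between wild-type males and females and by 2.01 between mutant males and females.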

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

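The tests of Kupffer against endothelial markers, of a batch, of a larger spread among mutants and of wrong sex labels were chosen only after the result was seen, as were the covariate and the fit without M2 mutant males 1 and 3.

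Matrix, stellate, Kupffer and lymphocyte genes were higher in M2 mutants. An equal rise of all other cell types was looked at with the Kupffer and endothelial scores, picked after their list counts were seen. The Kupffer mean went from 3.71 ± 0.12 to 4.72 ± 0.62 log2 CPM and the endothelial mean from 4.15 ± 0.26 to 4.38 ± 0.60. The difference between these shifts was 0.781 (exact permutation p = 0.00476, two-sided, 210 splits of 6 against 4 libraries, the smallest p these splits can give). These 2 scores did not rise alike. A lower share of hepatocyte RNA stays open, since the other cell types need not enter in equal parts. M2 mutant male 1, the M2 library with the highest marker means, does not account alone for the rise of matrix, Kupffer and stellate genes, since 22 of 37, 13 of 13 and 7 of 11 were higher without it. For lymphocyte markers its part stays open, since the number higher went from 11 to 4 of 12 without it, and the call of the stellate gene Ngfr was lost. With the covariate of other cell types' markers 5 matrix, 0 Kupffer, 1 stellate and 0 lymphocyte genes were higher, and the Col1a1 value went from 3.41 to 0.79 (adjusted p = 0.399), although that covariate contains several of the lists themselves. The numbers of lower metabolic genes of the hepatocyte shrank with it as well. A batch cannot be told apart from the group, since 0 libraries of other groups carry the label format of the 6 M2 mutants, and a change in the Kupffer, stellate or lymphocyte content of the mutant liver may also stand behind the values and was not tested.

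Changes of P14 mutants went the way of wild-type maturation for 553 higher and 448 lower genes. They went against it for 284 higher and 108 lower genes. Sharing the 5 wild-type P14 libraries does not explain the overlap, because with these libraries split between the comparisons the median number shared was 423, against 216 for independent lists (12 splits, range 348 to 493). The covariance of fold changes was 0.285, above the 0.0567 to 0.0669 of 20 simulations of unchanged groups. The correlation across genes was lower than in those simulations (r = 0.218 against a median of 0.474). An earlier onset of part of the adult programme in mutants is a candidate explanation that was not tested here.

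The sex difference was smaller in M2 mutants. Over the male-biased list the median log2 ratio of males to females was 4.27 in wild-type and 2.11 in mutants, with 16 and 12 of 17 genes called, and over the female-biased list −6.64 and −2.55, with 23 and 15 of 23 called. A larger spread among mutants with differences of the same size would leave the medians equal, but fry of limma gave adjusted p = 0.000928 for the male-biased and adjusted p = 0.000288 for the female-biased list. Wrong sex labels would show in Xist and Y-linked counts, which matched in 6 of 6 M2 mutant libraries. A batch of the M2 mutants stays open, since it cannot be told apart from the group, and growth hormone signalling, which sets sex bias in liver, was not tested.

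Regrouping the libraries within sex asked whether chance could give as many calls. Only the real grouping among 100 splits gave 2517 genes for the mutant at P14 (highest other 378) and 6070 at M2 (highest other 4329). The same held for age in mutant (5374, highest other 1203) and the change of the genotype effect with age (2930, highest other 111). It also held among 60 splits for age in wild-type (6737, highest other 5318). All possible splits were run for the mutant at M2 and for age in wild-type. The other sets of 100 were part of 210 (P14), 560 (age in mutant) and 21000 (the change) possible splits. The smallest share these splits can give is 1 of 100 or 1 of 60, which is under 0.05 but does not exclude chance. The highest other values for the mutant at M2 and age in wild-type came from splits that nearly swap the labels. For the mutant at M2 all wild-type libraries were labelled mutant, and for age all M2 libraries were labelled P14. Such splits hold much of the real difference with its sign turned. They do not show how many calls an unrelated grouping gives. For sex in mutants at M2 the 10 splits are too few for a share under 0.05. There 2 of 10 splits gave as many genes as the real 245, and the other, males 1 and 2 with female 2 against the rest, gave 665, which points to a structure of the samples other than sex.

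Only P14 mutant females, with 5 libraries, were a group large enough for the outlier test. There 10 of 91 tests, of genes, the library total and the Rn45s share, had a library far from the rest. Chance would mark about 1 in 20 independent tests of normal values, while related genes such as Mup3, Mup10 and Mup20 are not independent. Female 1 had low Eed (6.63 CPM, next 9.10) and Asl (377, next 515) and high Anxa2 (22.4, next 12.0) and Ngfr (9.33, next 3.63). Female 3 had high Mup3 (5.56 CPM, next 1.23), Mup20 (1.70, next 0.47) and Mup10 (0.234, next 0.0615). Female 4 had high A2m (13.6 CPM, next 4.92) and female 5 high Scd1 (1216 CPM, next 448) and Scd2 (57.58 CPM, next 21.5).

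The genotype effect differed between ages for 2930 genes, by the test of the difference itself. The following values are the effect at M2 minus that at P14, on the log2 scale. More negative effects at M2 were seen for Hamp at −8.54, Orm1 at −7.81, Hamp2 at −6.61, Thrsp at −6.40, Scd1 at −6.20, Mup3 at −5.57 and Orm3 at −5.50. Others were Nnmt at −4.79, Gsta2 at −4.59, Cyp2c38 at −4.28, Inmt at −4.07, Prodh at −4.02, Ces1b at −3.21, Cyp27a1 at −3.10, Asl at −1.87, Arg1 at −1.74, Cyp2f2 at −1.57, Ctsc at −1.37, Ugt2b1 at −1.04, Hnf4a at −0.93, Pygl at −0.92, Acp1 at −0.79 and Sntg2 at −3.94. More positive effects were seen for Igf2bp3 at 8.15, Gpc3 at 7.11, Igf2 at 6.998, Afp at 6.91, Hsd3b1 at 6.20, Ntrk2 at 5.37, Grb10 at 4.07, Cd24a at 3.24, Lhx2 at 2.86 and Socs2 at 2.59, and for Sult2a6 at 7.47, A2m at 7.395, Cd63 at 4.92, Ltf at 4.81, Col1a1 at 4.80, Bicc1 at 4.61, Anxa2 at 4.04, Slc13a3 at 3.97, Spp1 at 3.74, Cyp4a31 at 2.89, Ccna2 at 2.42, Ngfr at 2.06, Cdkn1a at 2.03, Marco at 2.005, Rhbg at 1.77, Elovl5 at 1.52 and Arrdc4 at 1.31. The values of Igf2bp3, Igf2, Sult2a6, A2m and Ltf rest on groups near 0 counts and depend on the prior count. Those of Gpc3, Hamp, Orm3, Col1a1, Gsta2, Cyp2c38, Hsd3b1 and Lhx2, among others, also rest on a wild-type group with few counts.

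The sex difference at M2 changed with genotype for 67 genes, of which 16 were not called by sex in wild-type. As mutant minus wild-type of the male minus female log2 difference, the values were Sult2a2 7.49, Cyp2b9 5.81, Ntrk2 5.30, Slc22a27 4.05, Nt5e 3.19, Evc 3.08, Sgk2 1.51, C6 −2.16, Selenbp2 −4.355 and Cyp4a12a −6.58. Those of Sult2a2 and Cyp4a12a rest on a wild-type group near 0 counts, and those of Ntrk2 and Evc on wild-type males with few counts.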

How the results depend on the processing

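The removal of ribosomal entries, the covariate of other cell types' markers, the fit without M2 mutant males 1 and 3 and the splits of the M2 libraries were chosen only after the result was seen. Of 135 pairs of a named gene and a comparison, 96 kept their direction and side of the threshold under every alternative run for them. Over all alternatives, gene-level calls gave 3116 unchanged, 71 weaker, 7 stronger and 17 reversed values. Counts of genes were within 1.5 times in 261 cases, lower in 64 and higher in 8, and counts of list members in 6595, 833 and 240. No scaling alternative moved the median log2 fold change by over 0.1. Each of them sets the typical gene near no change, so none can show a shift of most genes together.

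For genes higher in mutant at P14 and genes lower in mutant at P14, a log2 fold change of at least 1 gave 1026 and 217, males only 471 and 136, females only 838 and 470, the replicate block 1375 and 902, and single libraries left out 986 to 1611 and 481 to 984. For genes higher in mutant at M2 and genes lower in mutant at M2, males only gave 2049 and 1374, females only 1602 and 1032 and the covariate 1427 and 660. The fold minimum gave 344 lower, and single libraries left out 2769 to 3707 and 1659 to 2930. For genes higher at M2 in wild-type and genes lower at M2 in wild-type, the fold minimum gave 1149 and 1980, males only 1392 and 1553 and the covariate 1307 and 1387. For genes higher at M2 in mutant and genes lower at M2 in mutant, the fold minimum gave 908 and 790 and males only 564 and 589. For genes with genotype effect differing by age, the fold minimum gave 1854, males only 852, females only 804, the covariate 1924 and single libraries left out 1952 to 3737. Fits to 1 sex hold fewer libraries, and the fold minimum can only remove calls. The cause of the other changes was not tested.

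For genes differing by sex in wild-type at M2, fitting only the groups compared gave 2642 and single libraries left out 107 to 135. For genes differing by sex in mutant at M2, the DESeq2 Wald test gave 372, only the groups compared 87, the covariate 582 and single libraries left out 101 to 1232. For genes with sex difference changed in mutant at M2, the DESeq2 Wald test gave 243, limma-voom 38, limma-trend 106, the covariate 228 and single libraries left out 12 to 760. The cause was not tested. Groups of 2 or 3 libraries limit these comparisons, and the self-test called 8 of 100 2-fold changes of the sex difference.

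At a threshold of 0.01 the overlap of mutant P14 and wild-type age effects was 474, the overlap of mutant P14 and mutant M2 effects 626 and the overlap of mutant M2 and wild-type age effects, counted in opposite directions, 1658, and 12 splits of the P14 libraries gave a median of 423 for the first of these. With an estimated correlation 0 gene lists passed in each of the 5 comparisons. At P14 fry passed 5, the PRC2 subunits, developmental regulators, periportal genes, granulocyte markers and acute phase genes. Suz12 turned to 0.27 (females only) and 0.0398 (covariate) at P14 and to 0.22 (females only) at M2. Igf2 at P14 ran from −1.55 to 0.00146 with single libraries left out, the latter without mutant male 2. Ezh2 at M2 turned to 0.0179 with the 10-count filter, 0.0195 with only the groups compared, 0.0628 with the replicate block, 0.0743 in males only, 0.0103 without ribosomal entries and 0.0322 without mutant males 1 and 3, and ran from −0.18 to 0.23 without single libraries. Ngfr at M2 turned to −0.21 with the covariate. The sex difference of Sgk2 in wild-type ran from −0.0856 to 0.374 without single libraries. The cause was not tested.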

Other observations

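The comparison of per-library scores of lipid genes and their order by replicate number were chosen only after the result was seen, while the list tests were planned. Markers of bile duct cells and of Kupffer cells also fell with age in wild-type libraries. Of 9 cholangiocyte markers 6 fell and 0 rose, also adjusted over the list alone (median −2.27, or −1.56 at the bound, camera adjusted p = 0.0201, adjusted p = 0.4 with an estimated correlation). Of 13 Kupffer cell and macrophage markers 8 fell, also adjusted over the list alone, and 5 without M2 wild-type male 1 (median −0.80, camera adjusted p = 0.0301, adjusted p = 0.649 with an estimated correlation). Of 12 endothelial markers 6 fell, also adjusted over the list alone, and 3 without M2 wild-type male 1, but the list did not pass camera (median −0.70, adjusted p = 0.0722, adjusted p = 0.7 with an estimated correlation). The cholangiocyte markers averaged 0.958 ± 0.197 log2 CPM in 5 wild-type libraries at P14 and −0.22 ± 0.294 in 4 at M2, and 1.45 ± 0.338 in 7 mutant libraries at P14 and 2.30 ± 0.445 in 6 at M2. The change of the genotype effect with age was positive for 5 of 9 and negative for 0, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000148, adjusted p = 0.197 with an estimated correlation).

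Genes expressed by position along the lobule changed with age in mutants in another way than in wild-type, while the position of cells was not measured. Pericentral genes averaged 5.65 ± 0.0947 log2 CPM in P14 wild-type and 5.58 ± 0.217 in P14 mutants, and 5.19 ± 0.248 in M2 wild-type against 6.07 ± 0.169 in M2 mutants. With age in wild-type 5 of 15 pericentral genes rose and 7 fell (camera adjusted p = 0.461), and in mutants 8 rose and 1 fell (camera adjusted p = 0.0146, adjusted p = 0.308 with an estimated correlation). For periportal genes neither passed, with 5 of 12 up and 2 down in wild-type (camera adjusted p = 0.0605) and 4 up and 5 down in mutants (camera adjusted p = 0.483). The difference of the genotype effect between the ages was called positive for 6 of 15 pericentral genes and negative for 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00291, adjusted p = 0.199 with an estimated correlation). For periportal genes it was negative for 6 of 12 and positive for 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000555, adjusted p = 0.161 with an estimated correlation).

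Scores of lipid genes differed widely among the 7 P14 mutant libraries. The mean log2 CPM of cholesterol synthesis genes was 3.63 to 4.47 in the 5 wild-type libraries, and in mutants 4.14 in male 1, 7.34 in male 2 and 3.66, 3.62, 5.49, 6.67 and 6.15 in females 1 to 5. The mean of lipogenesis genes was 5.08 to 5.63 in wild-type, and in mutants 5.72 in male 1, 7.38 in male 2 and 5.63, 5.90, 6.91, 6.93 and 7.37 in females 1 to 5. The replicate numbers order these libraries within each sex, with male 1 and females 1 and 2 on the low side and male 2 and females 3 to 5 on the high side. The third principal component parted the same sets (−14.6 to −4.89 against −39.7 to −33.2). What the numbers stand for is not in the labels, so a difference in batch, litter or handling stays open.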
